A study of Mus musculus with 24 samples.

How the data were processed

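RNA was sequenced from mouse AKPS-iAPC organoids in 8 groups of 3 libraries, which cover every combination of divarasib (10 nM), doxycycline (200 ng/ml, called APC restoration in the labels) and GNE-7883 (1 µM), each given or not for 24 h after 3 days of growth. The treatment label of the 3 libraries with divarasib and GNE-7883 reads Diva_GDC-7883, while their titles and the growth protocol name GNE-7883, which was taken as the compound. Per the labels' protocols, RNA was extracted with a column kit with DNA digestion, libraries were made with the Illumina Stranded mRNA kit, and single-end reads were sequenced on a NovaSeq X Plus. Per the labels' processing notes, reads were aligned with GSNAP to GRCm38.p5, with no GSNAP version given.

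Each library has 1 deposited table with a count of reads per Ensembl gene, a width and an RPKM value per gene. The deposited count column holds whole numbers with a different total in each file, and these counts are the unit used here. The deposited RPKM values were used only to check the unit of the counts. The library total that they imply was worked back from the counts, the width and the RPKM, as a median over well-counted genes. It was 19.782 to 28.167 M. The counts assigned to genes were 83.21% to 87.15% of that inferred total. The counting program, the annotation release and the strand setting are not given in the labels or the files. Total counts per library ranged from 17.24 to 23.78 M, the mitochondrially encoded share from 1.164% to 2.734% and the share of the 10 most counted genes from 2.814% to 4.262%.

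Gene symbols were matched by Ensembl identifier to the reference table of gene names, which gave a symbol to 99.56% of the 52636 genes. Coordinates and overlaps were taken from the GENCODE annotation of GRCm38, 1-based. Genes with low counts were removed with edgeR's filterByExpr, which left 15659 genes. Libraries were scaled by TMM, with factors from 0.95323 to 1.0345. Differences were tested with edgeR 4.0.16 under R 4.3.3 by the quasi-likelihood F test, with robust dispersion estimates, 1 coefficient per group, all 24 libraries and 16 residual degrees of freedom, and Benjamini-Hochberg adjustment over all genes tested in each comparison. The common biological coefficient of variation was 0.0642. A standard error is the absolute log2 fold change divided by the square root of F. There were 20 comparisons, 7 against DMSO, 9 other pairwise comparisons in which 1 agent was added to others, and 4 interactions. CPM values are TMM-scaled, and principal components were computed on log2 CPM with a prior count of 2.

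Before the data were examined, 28 gene lists with 427 genes were fixed, and the 23 with at least 5 tested members were tested in each comparison with camera (limma 3.58.1, 2-sided, preset inter-gene correlation of 0.01, adjusted over the lists in a comparison), and again with a correlation estimated from the data. The genes to name were fixed by a rule beforehand. For each comparison with DMSO it takes the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 5 CPM whose replicates do not overlap those of DMSO, passing over predicted genes. For each other comparison or interaction it takes the 5 highest and 5 lowest in the same way, without the last condition for interactions. It also takes members of the fixed lists and the engineered genes Apc, Kras, Trp53 and Smad4. The text names fewer, in order of size, and which list members serve as examples was chosen after their values were seen.

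Alternatives fixed before the data were examined were DESeq2's size factors, no filter and a stricter filter on low counts (at least 1 CPM in 6 libraries), DESeq2 1.42.0's Wald test, the replicate number as a block, a fit of only the compared groups, and leaving out each library in turn. Leaving out APC restoration replicate 1 where its group was not part of the comparison, and for the gene lists (with either correlation) and correlations, was added after the data were seen. The replicate numbers are not stated to mark a shared culture, batch or day, so the fits reported have no block. DMSO is the control of 7 comparisons, so no overlap of calls between them was counted, and responses were correlated only between contrasts that share no library.

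The steps were tested on simulated data, with counts drawn from the means, library sizes and dispersions of these libraries and, in each comparison, 200 genes changed by known folds. For divarasib against DMSO (15566 genes) edgeR recovered 83.58% of genes changed 1.5-fold, 98.51% of those changed 2-fold and 98.48% of those changed 3-fold, with 14 false calls of 201. For GNE-7883 against DMSO (15574 genes) the shares were 92.54%, 97.01% and 100%, with 7 false calls of 200, and for the divarasib and GNE-7883 interaction (15568 genes) 74.63%, 97.01% and 98.48%, with 8 of 188. For the 3-way interaction (15576 genes) they were 49.25%, 88.06% and 95.45%, with 17 of 172. In each of these 4 comparisons camera called the cell cycle list when its members were lowered 1.5-fold and 0 of the other lists, with the preset and with the estimated correlation. Genes were drawn independently of each other, and libraries only from the mean of their group. The lack of other list calls therefore does not bear on correlated genes or on a library that stands apart. All other genes were unchanged in the tested contrast, so a comparison in which most genes change was not simulated. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.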

Results

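Gene expression was measured by RNA sequencing in mouse AKPS-iAPC intestinal tumour organoids, which carry a doxycycline-inducible Apc, after 24 h with or without each of 3 agents. Divarasib (10 nM), a KRAS G12C inhibitor, doxycycline (200 ng/ml), which restores APC, and GNE-7883 (1 µM), a TEAD inhibitor, were given alone, in each pair and together, on organoids grown for 3 days beforehand. This gave 8 groups of 3 libraries, 24 in all, with DMSO as the untreated group. Total counts per library ranged from 17.24 to 23.78 M, and 15659 of the 52636 genes in the files had enough counts to be tested. Log2 fold changes are given ± SE from edgeR's quasi-likelihood fit of all 24 libraries, with n = 3 libraries per group, and a gene is called higher or lower when its Benjamini-Hochberg adjusted p is under 0.05. Genes given as the highest, lowest or most changed are so by a naming rule, among called genes with a mean of at least 5 CPM and without predicted genes, and against DMSO only where replicates do not overlap. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries. Counts of a gene list's members are over all genes tested, and the count adjusted over the list alone is given where it differs. Each list was compared with the other genes by camera with a preset correlation. Where this called the list in the fit of all libraries, its adjusted p with an estimated correlation is given beside it.

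The libraries separated first by divarasib and then by APC restoration. The first principal component held 53.4% of the variance and the second 22.96%. DMSO and GNE-7883 libraries lay close together, as did the libraries with divarasib alone and with divarasib and GNE-7883. APC restoration replicate 1 stood apart from its group, at a least-squares share of 0.451 of the way from the other APC restoration libraries (-0.005 and 0.005) to the group given divarasib with APC restoration (0.997 to 1.005). Where leaving out this library changed the call of a gene list or of a named gene, the value without it is given.

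**Figure D1:**
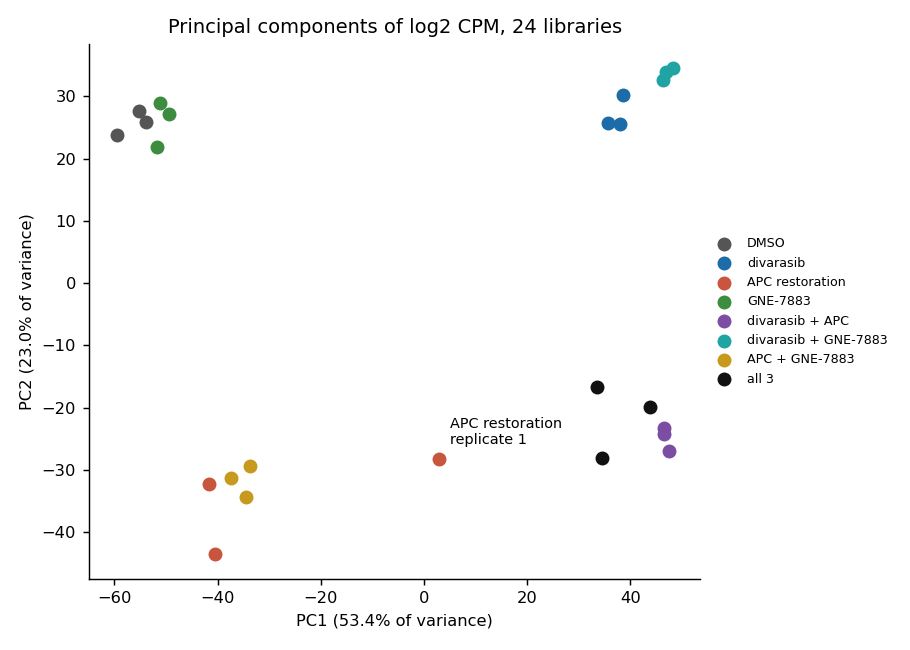
Scores of the 24 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, each point a library coloured by group. Divarasib separates the libraries along the first component and APC restoration along the second, and APC restoration replicate 1 lies between 2 groups.

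Apc, the transcript that doxycycline induces in this line (ENSMUSG00000005871, GRCm38 chromosome 18, 34220924 to 34322552, plus strand), was measured first as a check of the labels. Its mean was 207.5 CPM ± 6.506 (SD, n = 3) in DMSO and 1425 CPM ± 148.8 (SD, n = 3) with APC restoration, a log2 fold change of 2.78 ± 0.08 (edgeR adjusted p = 1.39e-17). The 12 libraries with doxycycline held 1248 to 1621 CPM of Apc and the 12 without it 195 to 248.7 CPM, so every library matched its doxycycline label. With divarasib, Apc was 0.21 ± 0.07 higher (edgeR adjusted p = 0.0176), a call that was lost without DMSO replicate 1 (0.0592), DMSO replicate 2 (0.0745) or divarasib replicate 2 (0.0691). Trp53, which encodes the tumour suppressor p53, was lower with divarasib (-0.58 ± 0.05) and with APC restoration (-0.43 ± 0.05). Kras was not called with any single agent, with log2 fold changes of 0.02 ± 0.05, 0.02 ± 0.05 and 0.04 ± 0.05 for divarasib, APC restoration and GNE-7883. Smad4 was not called with divarasib (0.05 ± 0.05, edgeR adjusted p = 0.303), although it was with a stricter filter on low counts (0.0136), nor with APC restoration (-0.06 ± 0.05) or GNE-7883 (-0.02 ± 0.05). These counts do not show which allele or transgene a read came from.

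**Figure D2:**
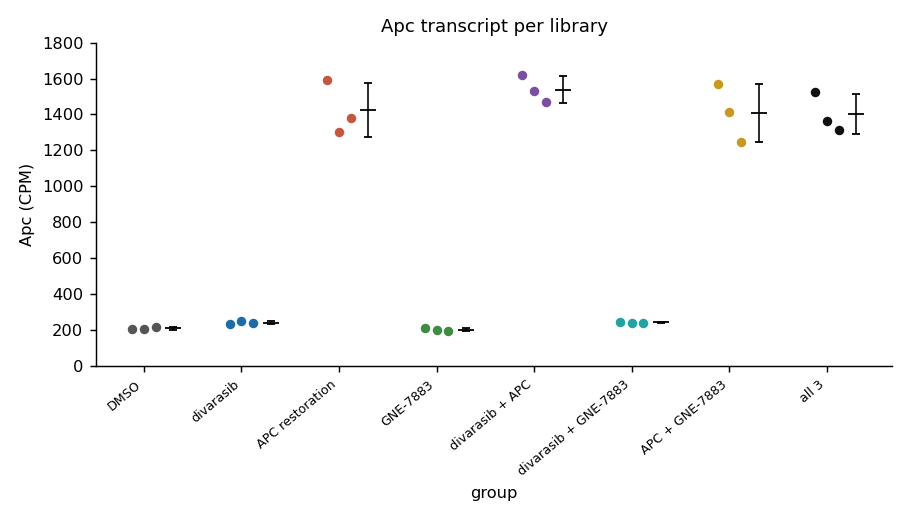
Apc in CPM (y axis) in each library (points) of the 8 groups (x axis), with the group mean and SD (bars, n = 3). The 12 libraries with doxycycline lie between 1248 and 1621 CPM and the others between 195 and 248.7 CPM.

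The comparison of divarasib with DMSO asks what KRAS G12C inhibition changes on its own. The direct output of the ERK pathway fell, with 14 of 16 tested members lower and 1 higher (camera adjusted p = 1.85e-09; adjusted p = 0.23 with an estimated correlation, or 0.00149 without APC restoration replicate 1). The largest falls among them were in Spry4 (-4.95 ± 0.33), which encodes a feedback inhibitor of the pathway, and in the ETS transcription factor genes Etv5 (-4.22 ± 0.28) and Etv4 (-3.85 ± 0.25). Spry4 had 426 counts in the 3 DMSO libraries and 15 in the 3 divarasib libraries. Fosl1, an AP-1 subunit (-3.09 ± 0.23), and the ERK phosphatase gene Dusp6 (-2.30 ± 0.18) fell too, and the member that rose was the ephrin receptor gene Epha4 (0.93 ± 0.07). Cell cycle genes fell together, 29 of 29 members, with a median log2 fold change of -1.31 (camera adjusted p = 2.22e-29; adjusted p = 0.147 with an estimated correlation, or 0.0375 without APC restoration replicate 1). Among them were Ccne2, cyclin E2 (-1.77 ± 0.11), and the transcription factor gene Mybl2 (-1.68 ± 0.10). Genes of ribosome biogenesis also fell, 20 of 20 (camera adjusted p = 3.28e-22; adjusted p = 0.147 with an estimated correlation, or 0.00638 without APC restoration replicate 1), and Myc itself was lower (-1.61 ± 0.10).

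Other gene groups moved with divarasib in both directions. Of 19 tested YAP/TEAD targets 13 rose and 4 fell (camera adjusted p = 0.00502; adjusted p = 0.409 with an estimated correlation). Tgfb2 (2.67 ± 0.35), Ccdc80 (2.48 ± 0.33), Ccn1 (1.18 ± 0.14) and Ankrd1 (1.00 ± 0.12) were higher, and Dock5 (-0.82 ± 0.10) and F3, tissue factor (-0.62 ± 0.11), lower. Of 12 tested BCL2 family and BH3 genes 9 rose and 1 fell (camera adjusted p = 0.00212; adjusted p = 0.296 with an estimated correlation), led by Bmf (2.81 ± 0.23), and Pmaip1 (1.14 ± 0.11) was also higher. Both encode BH3-only proteins, which promote apoptosis. Genes of the integrated stress response (17 of 21 lower, 2 higher), cholesterol synthesis (18 of 19 lower, 1 higher) and glycolysis and hypoxia (16 of 17 lower, 1 higher) fell, with camera adjusted p of 2.98e-06, 4.54e-07 and 0.000836 (adjusted p = 0.404, 0.404 and 0.483 with an estimated correlation). With an estimated correlation and without APC restoration replicate 1 the stress response list was called (0.00344) and the other 2 were not. Trib3, a stress response target, fell by 2.15 ± 0.21 on the log2 scale. Wnt/beta-catenin targets were split, 8 higher and 8 lower of 19 (camera adjusted p = 0.235), with Notum (1.13 ± 0.22) and Tnfrsf19 (1.03 ± 0.12) higher and Ephb2 (-1.49 ± 0.13) lower. Of 12 receptor tyrosine kinases and EGF ligands 8 rose and 3 fell (camera adjusted p = 0.235, or 0.0279 with no filter on low counts), including the receptor gene Fgfr3 (2.15 ± 0.27) and the ligand gene Areg (-1.71 ± 0.22).

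Across all genes, 5166 were higher and 5212 lower with divarasib, 10378 in total, of which 2580 changed at least 2-fold. The larger side turned to 5522 higher and 4297 lower with a stricter filter on low counts, and turned also with no filter, DESeq2's size factors, its Wald test and without divarasib replicate 1. The largest rises by the naming rule were in Igfbp5, a growth factor binding protein gene (5.80 ± 0.73, or 6.72 without DMSO replicate 2, from 18 counts in the 3 DMSO libraries to 1152), Cym, chymosin (5.51 ± 0.60), the small heat shock protein gene Cryab (5.03 ± 0.48), the cytokine gene Il18 (4.77 ± 0.40) and Plet1 (4.11 ± 0.41). The largest falls were in Stc1, a secreted glycoprotein gene (-4.36 ± 0.41), Etv5, Rasal1, a Ras GTPase-activating protein gene (-3.99 ± 0.36), Etv4 and the mucin gene Muc5ac (-3.64 ± 0.64). With 10378 of 15659 genes called, TMM's assumption that most genes do not change is strained, so fold changes are relative to the bulk of the genes.

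**Figure D3:**
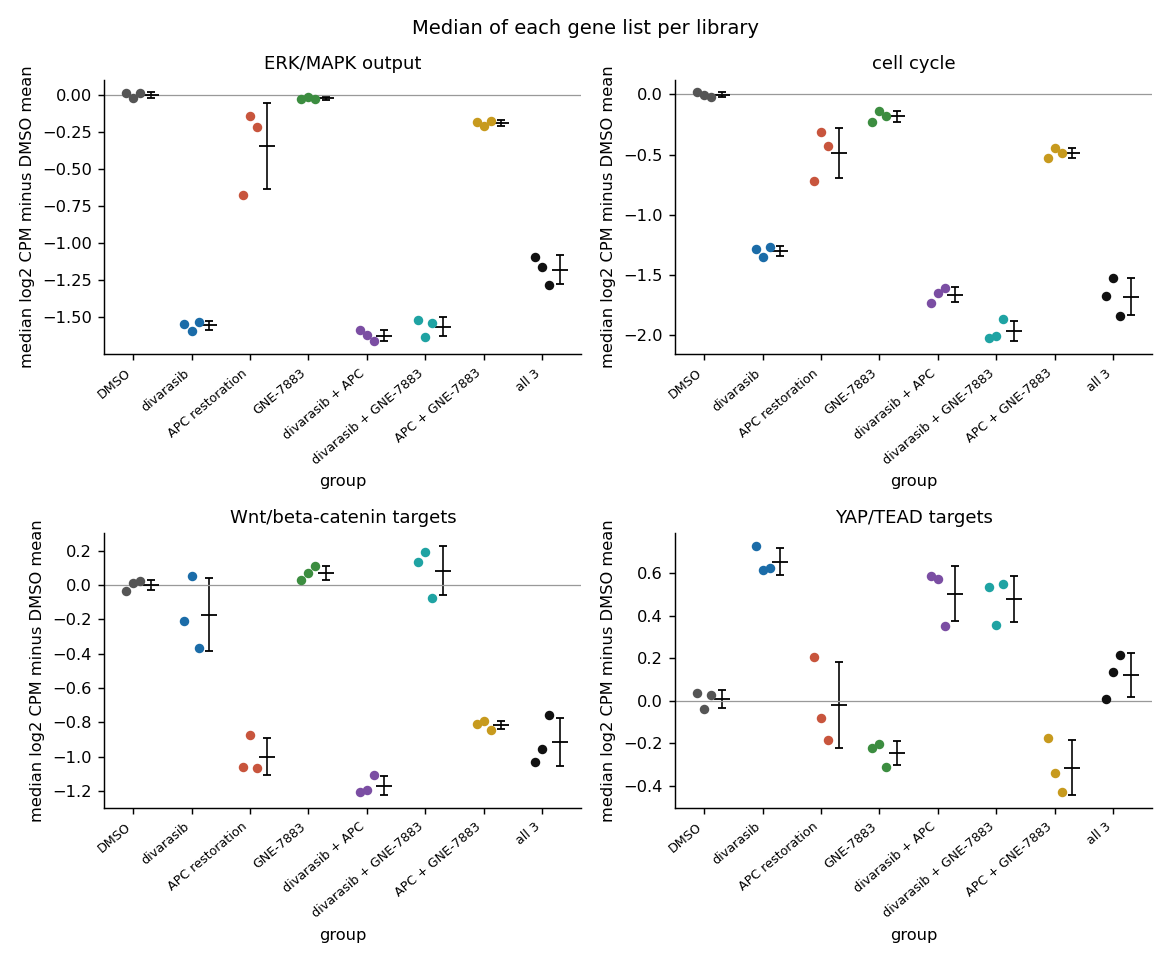
Median over the tested members of 4 gene lists (panels) of log2 CPM minus the mean of the DMSO libraries (y axis) in each library (points) of the 8 groups (x axis), with the group mean and SD (bars, n = 3). ERK output and cell cycle medians are lowest in the groups with divarasib, Wnt/beta-catenin target medians in the groups with APC restoration, and YAP/TEAD target medians are below DMSO in all 3 GNE-7883 libraries.

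The comparison of APC restoration with DMSO asks what returning APC does on its own. Wnt/beta-catenin targets fell, 18 of 19 tested members (camera adjusted p = 1.88e-19; adjusted p = 0.00209 with an estimated correlation), and so did crypt stem cell markers, 14 of 15, with 1 higher (1.13e-14; adjusted p = 0.0075 with an estimated correlation). Lgr5, the receptor gene that marks intestinal stem cells (ENSMUSG00000020140, GRCm38 chromosome 10, 115450311 to 115587780, minus strand), fell from 117.7 CPM ± 10.15 to 30.06 CPM ± 6.094 (SD, n = 3), a log2 fold change of -1.98 ± 0.13. The transcription factor gene Prox1 (-1.82 ± 0.16) and the feedback inhibitor genes Nkd1 (-1.78 ± 0.16) and Axin2 (-1.43 ± 0.10) fell as well. Absorptive enterocyte markers rose, 17 of 21 and 18 adjusted over the list alone (camera adjusted p = 2.23e-14; adjusted p = 0.0195 with an estimated correlation), such as Alpi, intestinal alkaline phosphatase (3.99 ± 0.28), and the keratin gene Krt20 (3.94 ± 0.16). Goblet cell markers rose too, 7 of 11 (camera adjusted p = 0.000215; adjusted p = 0.223 with an estimated correlation), such as Muc2, the main intestinal mucin (4.09 ± 0.46), Tff3 (4.37 ± 0.39) and Fcgbp (4.27 ± 0.41). Muc2 stayed low in counts, with 22 in the 3 DMSO libraries and 326 in the 3 with APC restoration.

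Other gene lists also moved with APC restoration. Cell cycle genes were lower in 29 of 29 members with a median of -0.47 (camera adjusted p = 5.8e-11; adjusted p = 0.318 with an estimated correlation), and ribosome biogenesis genes in 17 of 20 (3.85e-06; adjusted p = 0.427 with an estimated correlation). The cell cycle medians against the DMSO mean were -0.715, -0.315 and -0.431 in APC restoration replicates 1, 2 and 3. ERK output was lower in 10 of 16 members (camera adjusted p = 0.00968; adjusted p = 0.56 with an estimated correlation), but without APC restoration replicate 1 in 7, with 1 higher (camera adjusted p = 0.0338). Receptor tyrosine kinases and EGF ligands were higher in 8 of 12 (0.00205; adjusted p = 0.0315 with an estimated correlation), including Erbb3 (0.81 ± 0.04) and Erbb2 (0.69 ± 0.05). Fetal or regenerative epithelium genes were higher in 10 of 16 and lower in 1, or 2 adjusted over the list alone (camera adjusted p = 0.000237; adjusted p = 0.141 with an estimated correlation). Bmf was 1.82 ± 0.25 higher, or 1.28 without APC restoration replicate 1.

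In all, 3246 genes were higher and 3663 lower with APC restoration, 983 of them at least 2-fold. Without APC restoration replicate 1 the total was 6546 in place of 6909, of which 5660 were called in both fits, and 951 were at least 2-fold. The larger side turned to 3607 higher and 3017 lower with a stricter filter on low counts, 3527 and 2833 with no filter, 2513 and 1795 in a fit of the 2 groups alone, and 3476 and 2808 without APC restoration replicate 3. The largest rises by the naming rule were in Zg16, a goblet cell secretory protein gene (6.01 ± 0.67), Clec2h (5.42 ± 0.42), the sulfotransferase gene Sult1d1 (5.14 ± 0.25), the cytochrome P450 gene Cyp2c66 (4.41 ± 0.41) and the glutathione transferase gene Gsta1 (4.37 ± 0.16). The largest falls were in Pgc, pepsinogen C (-2.41 ± 0.86), the mucin gene Muc6 (-2.34 ± 0.46), the phospholipase gene Pla2g2a (-2.31 ± 0.38, or -3.00 without APC restoration replicate 1), the sodium-proton exchanger gene Slc9a3 (-2.27 ± 0.27) and Pla2g2f (-2.24 ± 0.25). The call of Pgc was lost without DMSO replicate 1, DMSO replicate 3 or any 1 of the 3 APC restoration libraries (edgeR adjusted p from 0.0513 to 0.114, the highest without APC restoration replicate 1). A fit of the 2 groups alone called 4308 genes in place of 6909, and doxycycline was not given to organoids that lack the inducible Apc, so its own effects are not separated from those of APC.

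The comparison of GNE-7883 with DMSO asks what TEAD inhibition changes on its own. Fewer genes were called than with divarasib or APC restoration alone, and most changed by less than 2-fold. YAP/TEAD targets fell, 7 of 19 tested members and 8 adjusted over the list alone (camera adjusted p = 2.71e-12; adjusted p = 0.0433 with an estimated correlation). Among them were Ccn2, a matricellular protein gene (-0.94 ± 0.10), Ankrd1 (ENSMUSG00000024803, GRCm38 chromosome 19, 36111961 to 36120099, minus strand), Amotl2 (-0.88 ± 0.13), Ccn1 (-0.74 ± 0.15) and Crim1 (-0.53 ± 0.06). Ankrd1 fell from 76.37 CPM ± 3.113 to 40.61 CPM ± 6.539 (SD, n = 3; -0.91 ± 0.13). Of 17 Hippo pathway and TEAD genes 5 fell, including Amotl1 (-0.74 ± 0.09) and Tead4 (-0.50 ± 0.08) (camera adjusted p = 0.00204; adjusted p = 0.392 with an estimated correlation). Cell cycle genes had a median of -0.18, with 1 of 29 members lower, or 8 adjusted over the list alone and 11 over all genes without APC restoration replicate 1 (camera adjusted p = 1.17e-08; adjusted p = 0.392 with an estimated correlation). Integrated stress response genes were lower in 2 of 21, or 9 adjusted over the list alone (3.95e-07; adjusted p = 0.392 with an estimated correlation). Leaving out APC restoration replicate 1 gave 12 of 21 and an adjusted p of 0.00191 with an estimated correlation.

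GNE-7883 changed 523 genes, 304 higher and 219 lower, with 29 at least 2-fold, or from 7 without GNE-7883 replicate 3 to 54 without APC restoration replicate 1. The largest rise by the naming rule was in Wfdc18 (1.47 ± 0.26). The largest falls were in the noncoding RNA Mirt1 (-1.52 ± 0.12), Sez6l2 (-1.16 ± 0.16), the RNA-binding protein gene Igf2bp1 (-1.15 ± 0.08) and the extracellular matrix gene Efemp1 (-0.98 ± 0.16). The count was 1425 without APC restoration replicate 1, 194, 262 and 187 without DMSO replicates 1, 2 and 3, and 176 and 142 without GNE-7883 replicates 1 and 3. The call of Ccn1 was lost without GNE-7883 replicate 1 (edgeR adjusted p = 0.059) or 3 (0.0717). A fit of the 2 groups alone called 1369 genes and not Wfdc18 (0.0513), DESeq2's Wald test called 826, and with no filter on low counts 1247 were called.

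**Figure D4:**
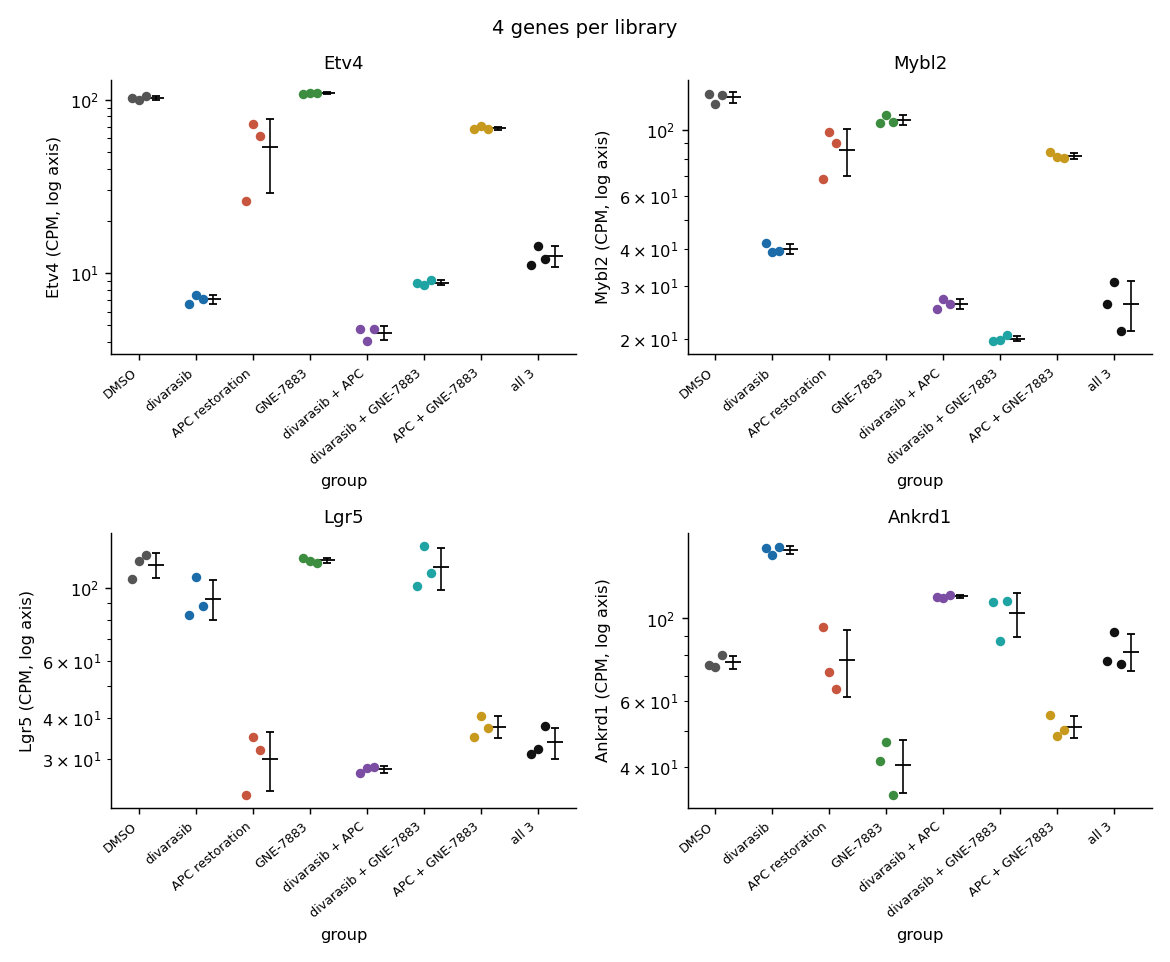
Expression in CPM on a log axis (y axis) of Etv4, Mybl2, Lgr5 and Ankrd1 (panels) in each library (points) of the 8 groups (x axis), with the group mean and SD (bars, n = 3). Etv4 falls in the groups with divarasib, from 102.4 CPM in DMSO to 7.077 CPM with divarasib alone, and Lgr5 falls in the groups with APC restoration, from 117.7 to 30.06 CPM with APC restoration alone.

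Divarasib with APC restoration showed changes of both agents against DMSO. Wnt/beta-catenin targets were lower in 17 of 19 members (camera adjusted p = 5.84e-08; adjusted p = 0.0788 with an estimated correlation), and ERK output in 13 of 16, with 1 higher (5.84e-08; adjusted p = 0.149 with an estimated correlation, or 0.00302 without APC restoration replicate 1). Absorptive enterocyte markers were higher in 20 of 21 (camera adjusted p = 2.85e-07; adjusted p = 0.105 with an estimated correlation). Cd36, a fatty acid transporter gene, had 3 counts in the 3 DMSO libraries and 756 in the 3 combination libraries, a normalised ratio of 244 (95% counting interval, exact binomial, 83.2 to 1190). Its log2 fold change of 7.76 in edgeR's fit was 8.56 without DMSO replicate 2. Zg16 (6.71 ± 0.65), Clec2h (5.90 ± 0.41), the prostaglandin transporter gene Slco2a1 (5.79 ± 0.25) and Igfbp5 (5.76 ± 0.73, or 6.67 without DMSO replicate 2) followed. The lowest were Etv5 (-5.47 ± 0.32), Rgcc (-5.30 ± 0.28), Stc1 (-5.21 ± 0.47), Etv4 (-4.50 ± 0.27) and the lactate transporter gene Slc16a3 (-3.77 ± 0.43). In all, 5439 genes were higher and 5420 lower, and the larger side turned in a fit of the 2 groups alone (5564 and 5614) and without DMSO replicate 1, 2 or 3.

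Against divarasib alone, adding APC restoration lowered Wnt/beta-catenin targets (14 of 19, 16 adjusted over the list alone) and crypt stem cell markers (14 of 15), each with a camera adjusted p of 2.71e-24 (adjusted p = 0.000472 with an estimated correlation). Lgr5 (-1.74 ± 0.13) and Axin2 (-1.48 ± 0.10) were among them. Absorptive enterocyte markers rose, 15 of 21 and 18 adjusted over the list alone (camera adjusted p = 1.25e-14; adjusted p = 0.0139 with an estimated correlation). Goblet cell markers rose in 8 of 11, or 9 adjusted over the list alone, with 1 lower (3.27e-06; adjusted p = 0.119 with an estimated correlation). The largest rises were in Zg16 (5.39 ± 0.55, or 6.001 without divarasib replicate 3), Sult1d1 (4.51 ± 0.21), Gsta1 (3.91 ± 0.17), Clec2h (3.83 ± 0.31) and Clca1, a goblet cell product (3.81 ± 0.41). The largest falls were in Slc9a3 (-2.14 ± 0.31), Slc16a3 (-2.06 ± 0.43), Pla2g2f (-2.02 ± 0.28) and Pla2g2a (-1.84 ± 0.34). In all, 2458 genes were higher and 2016 lower, although a stricter filter on low counts turned the split to 2012 higher and 2567 lower, as did no filter (2096 and 2277) and leaving out any 1 of the 3 libraries of the pair.

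Against APC restoration alone, adding divarasib lowered ERK output (13 of 16, with 3 higher, camera adjusted p = 9.82e-11; adjusted p = 0.177 with an estimated correlation, or 0.000817 without APC restoration replicate 1) and cell cycle genes (29 of 29, median -1.24, 2.09e-42; adjusted p = 0.0863 with an estimated correlation, or 0.019 without APC restoration replicate 1). YAP/TEAD targets rose in 13 of 19 and fell in 3 (camera adjusted p = 0.00472; adjusted p = 0.316 with an estimated correlation). The largest rises were in Cym (3.64 ± 0.54), Cryab (2.80 ± 0.40), Il18 (2.56 ± 0.29), the transcription factor gene Tbx2 (2.53 ± 0.41) and the aminopeptidase gene Anpep (2.46 ± 0.48). Without APC restoration replicate 1 their log2 fold changes were 5.86, 4.35, 3.49, 4.20 and 3.83. The largest falls were in Muc5ac (-4.32 ± 0.58, or -3.66 without APC restoration replicate 3), Etv5 (-4.17 ± 0.34), Tcf23 (-4.16 ± 0.43), Etv4 (-3.54 ± 0.28) and Slc16a3 (-3.31 ± 0.43). In all, 4513 genes were higher and 4413 lower, a split that turned in a fit of the 2 groups alone (3587 and 3731) and without APC restoration replicate 2 or 3 or any 1 library of the pair. The number changed at least 2-fold was 1585, or 2306 without APC restoration replicate 1.

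The interaction of divarasib and APC restoration asks which genes responded to the pair differently from the sum of the log2 effects of each alone. Cyp4b1, a cytochrome P450 gene (ENSMUSG00000028713, GRCm38 chromosome 4, 115624725 to 115647723, minus strand), had the largest positive interaction by the naming rule (2.06 ± 0.12). Its means were 68.23 CPM in DMSO, 15.24 with divarasib, 41.73 with APC restoration and 38.69 with both. Ppargc1a, a transcriptional coactivator of mitochondrial biogenesis, followed (1.14 ± 0.09). The most negative were Upk3b, a uroplakin gene (-2.31 ± 0.32), the calcium-binding protein gene S100g (-2.23 ± 0.39) and Aldh3b2 (-2.22 ± 0.42), which were -1.90, -1.86 and -1.76 without APC restoration replicate 1. Epithelial markers had 3 of 13 negative interactions, or 4 adjusted over the list alone, among them the keratin genes Krt8 (-0.67 ± 0.08) and Krt19 (-0.66 ± 0.09) (camera adjusted p = 0.000105; adjusted p = 0.726 with an estimated correlation). Ribosome biogenesis genes had 2 of 20 positive, or 4 adjusted over the list alone (8.72e-06; adjusted p = 0.726 with an estimated correlation). In all, 382 interactions were positive and 573 negative, and the total of 955 was 581 without DMSO replicate 3, 588 without divarasib replicate 3 and 1999 without APC restoration replicate 2. Without APC restoration replicate 1 the total was 896, of which 685 were called in both fits, and 89 in place of 118 were at least 2-fold. The split depended on the processing, with 168 positive and 1171 negative under a stricter filter, 76 and 702 in a fit of the 4 groups alone, and 1573 called in total with no filter. It turned to 469 positive and 406 negative without DMSO replicate 1, and to 348 and 342 without DMSO replicate 2.

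Divarasib with GNE-7883 lowered cell cycle genes against DMSO in 29 of 29 members, with a median log2 fold change of -1.96 (camera adjusted p = 2.72e-47; adjusted p = 0.0535 with an estimated correlation, or 0.00638 without APC restoration replicate 1). The largest rises against DMSO were in Cym (5.92 ± 0.60), Igfbp5 (5.76 ± 0.73, or 6.66 without DMSO replicate 2) and Il18 (4.70 ± 0.41), and the largest falls in Stc1 (-3.94 ± 0.40), Muc5ac (-3.83 ± 0.67) and Etv4 (-3.54 ± 0.25). In all, 5604 genes were higher and 5180 lower.

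Against divarasib alone, adding GNE-7883 lowered cell cycle genes further, 29 of 29, with a median of -0.69 (camera adjusted p = 1.35e-66; adjusted p = 0.0124 with an estimated correlation). Mybl2, a cell cycle transcription factor (ENSMUSG00000017861, GRCm38 chromosome 2, 163054687 to 163084688, plus strand), fell from 39.97 CPM ± 1.489 to 20.03 CPM ± 0.4247 (SD, n = 3; -0.996 ± 0.11). Rrm2, a ribonucleotide reductase subunit gene, fell by 0.92 ± 0.08 on the log2 scale. YAP/TEAD targets were lower in 8 of 19 (camera adjusted p = 3.87e-07; adjusted p = 0.123 with an estimated correlation) and cholesterol synthesis genes in 17 of 19 (1.25e-17; adjusted p = 0.123 with an estimated correlation). Without APC restoration replicate 1 these were 0.0406 and 0.0417 with an estimated correlation. The largest rises were in the ribonuclease gene Rnase1 (1.46 ± 0.22) and AW112010 (1.33 ± 0.17), and the largest falls in the myelin protein gene Pmp22 (-1.55 ± 0.21), the noncoding RNA Eprn (-1.32 ± 0.19) and Mirt1 (-1.31 ± 0.12). In all, 846 genes were higher and 1140 lower, or 625 and 1346 with DESeq2 size factors. The total of 1986 was 1250 without divarasib replicate 1, 3119 without APC restoration replicate 1 and 3128 in a fit of the 2 groups alone.

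Against GNE-7883 alone, adding divarasib changed 10729 genes, and ERK output and cell cycle genes were again lower. Cell cycle genes fell in 29 of 29 members (camera adjusted p = 4.65e-47; adjusted p = 0.0555 with an estimated correlation, or 0.00986 without APC restoration replicate 1), with a median of -1.81. ERK output fell in 13 of 16 members and rose in 2 (camera adjusted p = 3.12e-07; adjusted p = 0.294 with an estimated correlation, or 0.00259 without APC restoration replicate 1). The largest rises were in Cym (5.72 ± 0.59), Igfbp5 (5.58 ± 0.71) and the cholecystokinin receptor gene Cckar (4.79 ± 0.97), and the largest falls in Muc5ac (-4.57 ± 0.66), Stc1 (-4.03 ± 0.40) and the carboxylesterase gene Ces2a (-3.72 ± 0.37).

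The interaction of divarasib and GNE-7883 asks which genes responded to the pair differently from the sum of the log2 effects of each alone. Cell cycle genes were lower with the pair than that sum. Of 29 members 16 had a negative interaction, or 28 adjusted over the list alone, with a median of -0.50 (camera adjusted p = 2.08e-49; adjusted p = 0.0443 with an estimated correlation), and 25 without APC restoration replicate 1. Among them were Mybl2 (-0.75 ± 0.15), Ccne2 (-0.74 ± 0.16) and Rrm2 (-0.65 ± 0.11). Mitochondrially encoded genes had a median interaction of -1.05 (-0.815 without GNE-7883 replicate 1) with none of 13 called, or 13 adjusted over the list alone (camera adjusted p = 2.28e-16; adjusted p = 0.087 with an estimated correlation). By the naming rule the largest positive interactions were in Rnf39 (0.69 ± 0.13) and the immediate early gene Egr1 (0.61 ± 0.13), and the most negative in the centromere protein gene Cenps (-0.92 ± 0.21) and the keratin gene Krt79 (-0.85 ± 0.18). In all, 15 interactions were positive and 107 negative. The total of 122 was 367 without APC restoration replicate 1, 46 and 74 without DMSO replicates 2 and 3, 27 and 30 without divarasib replicates 1 and 3, 48 and 52 without GNE-7883 replicates 2 and 3, and 47 and 30 without replicates 1 and 2 of the pair. Leaving out 1 library ended the call of Cenps for 10 libraries (edgeR adjusted p up to 0.142, without divarasib replicate 1), Krt79 for 9 (up to 0.09, without replicate 2 of the pair) and Ccne2 for 7 (up to 0.103, without divarasib replicate 3). It ended that of Egr1 for 6 (up to 0.09, without replicate 2 of the pair), Mybl2 for 4 (up to 0.0769, without divarasib replicate 1) and Rnf39 for 3 (up to 0.0587, without divarasib replicate 3), while Rrm2 stayed called without each of the 12. DESeq2's Wald test called 277, no filter on low counts 635 and a fit of the 4 groups alone 583.

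APC restoration with GNE-7883 lowered Wnt/beta-catenin targets against DMSO (17 of 19, camera adjusted p = 9.31e-16; adjusted p = 0.00476 with an estimated correlation) and raised absorptive enterocyte markers (18 of 21, 2.95e-15; adjusted p = 0.0142 with an estimated correlation). The largest rises were in Zg16 (5.62 ± 0.68), Clec2h (5.25 ± 0.42) and Sult1d1 (5.04 ± 0.25), and the largest falls in the zinc transporter gene Slc30a2 (-1.79 ± 0.36), Igfbp1 (-1.75 ± 0.32) and Slc9a3 (-1.74 ± 0.25). In all, 2782 genes were higher and 3313 lower. The larger side turned to 3102 higher and 2658 lower with a stricter filter, 3039 and 2378 with no filter and 3570 and 3305 in a fit of the 2 groups alone. Against GNE-7883 alone, adding APC restoration lowered Wnt/beta-catenin targets in 16 of 19 (camera adjusted p = 5.09e-22; adjusted p = 0.000826 with an estimated correlation). It raised absorptive enterocyte markers in 17 of 21, or 18 adjusted over the list alone, with 1 lower (2.96e-17; adjusted p = 0.0092 with an estimated correlation). Clec2h (5.38 ± 0.43), Sult1d1 (4.98 ± 0.24) and Zg16 (4.47 ± 0.59) rose most, and Pgc (-2.72 ± 0.73), Pla2g2a (-2.46 ± 0.34) and the RNA-binding protein gene Msi1 (-2.43 ± 0.33) fell most, with 2480 genes higher and 2501 lower in all. Without GNE-7883 replicate 3 Zg16 was 5.53 and Pgc -1.54. A stricter filter gave 2740 and 1975, and the larger side turned also with no filter, the replicate block (2467 and 2453), DESeq2's Wald test, a fit of the 2 groups alone, and without GNE-7883 replicate 1 or any 1 library of the pair. The call of Pgc was lost without GNE-7883 replicate 3 (edgeR adjusted p = 0.0966) and in a fit of the 2 groups alone (0.101).

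Against APC restoration alone, adding GNE-7883 called 17 genes higher and 78 lower. YAP/TEAD targets were lower in 4 of 19 members, or 7 adjusted over the list alone and 2 without APC restoration replicate 1 (camera adjusted p = 3.48e-07; adjusted p = 0.144 with an estimated correlation). Ccn1 (-0.77 ± 0.16), Amotl2 (-0.73 ± 0.13), Ankrd1 (-0.60 ± 0.13) and Crim1 (-0.28 ± 0.06) were called. By the naming rule the largest rise was in Slc25a35 (0.56 ± 0.12). The largest falls were in the serpin gene Serpinb9b (-1.75 ± 0.32, or -1.08 without APC restoration replicate 1), the surfactant protein gene Sftpd (-1.01 ± 0.20) and Mirt1 (-0.93 ± 0.12). Cell cycle genes had no call in 29 members (camera adjusted p = 0.642, or 2.51e-07 without APC restoration replicate 1). With an estimated correlation the list was not called, with or without that library. Its medians against the DMSO mean were -0.528, -0.444 and -0.485 in replicates 1, 2 and 3 of the pair. With APC restoration alone they were -0.715, -0.315 and -0.431. The total of 95 was 212, 533 and 209 without APC restoration replicates 1, 2 and 3, and 21, 29 and 59 without replicates 1, 2 and 3 of the pair. Mirt1 stayed called without each of the 6 libraries, but leaving out replicate 1 or replicate 2 of the pair ended each of the other 7 calls (edgeR adjusted p up to 0.182, Crim1 without replicate 1). Leaving out its replicate 3 ended those of Slc25a35, Sftpd, Ccn1 and Ankrd1 (up to 0.112), and leaving out APC restoration replicate 1 ended those of Sftpd (0.084), Ankrd1 (0.095) and Crim1 (0.074). A fit of the 2 groups alone called 0 genes (889 at an unadjusted p under 0.05), DESeq2's Wald test called 270, and edgeR with no filter on low counts 675.

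The interaction of APC restoration and GNE-7883 held 2 positive and 15 negative genes. Igf2bp1 (0.58 ± 0.11) and the transporter gene Abcc5 (0.43 ± 0.07) were the positive ones, and the protease gene Prss32 (-0.75 ± 0.14) and the adhesion gene Nectin4 (-0.70 ± 0.13) the most negative by the naming rule. The difference between the YAP/TEAD response with and without APC restoration was not called for any of 19 members (camera adjusted p = 0.0594; adjusted p = 0.592 with an estimated correlation). The list was called, with a positive median of 0.21, without APC restoration replicate 1 (camera adjusted p = 1.97e-05; adjusted p = 0.334 with an estimated correlation), and with no filter on low counts (0.0382). The total of 17 ranged from 0 without GNE-7883 replicate 1 or 3 to 699 without APC restoration replicate 2, and all 12 libraries of the 4 groups moved it by over 1.5 times. Leaving out 1 library ended the calls of Igf2bp1, Prss32 and Nectin4 for 8 libraries each (edgeR adjusted p up to 0.202 without DMSO replicate 3, and 0.147 and 0.162 without GNE-7883 replicate 3) and of Abcc5 for 5 (up to 0.0911, without replicate 3 of the pair). A fit of the 4 groups alone called 0 genes (1780 at an unadjusted p under 0.05), DESeq2's Wald test 224 and edgeR with no filter 821.

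With all 3 agents, cell cycle genes were lower than in DMSO in 29 of 29 members (camera adjusted p = 1.01e-39; adjusted p = 0.0826 with an estimated correlation, or 0.00747 without APC restoration replicate 1). Zg16 (6.66 ± 0.65), Clec2h (6.12 ± 0.40) and Igfbp5 (5.69 ± 0.74, or 6.60 without DMSO replicate 2) rose most against DMSO, and Stc1 (-4.33 ± 0.43), Slc16a3 (-3.55 ± 0.43) and Faim2 (-3.54 ± 0.32) fell most. In all, 5261 genes were higher and 5173 lower, and the larger side turned in a fit of the 2 groups alone (4941 and 5005) and without DMSO replicate 1, 2 or 3. Against the pair of divarasib and APC restoration, adding GNE-7883 raised ERK output in 9 of 16 members and lowered 1, with a median of 0.44 (camera adjusted p = 9.49e-11; adjusted p = 0.084 with an estimated correlation, or 0.00157 without APC restoration replicate 1). Etv5 (2.29 ± 0.41), Spry4 (2.19 ± 0.43) and Etv4 (1.46 ± 0.31) rose, although Etv4 at 12.53 CPM stayed below its 102.4 CPM in DMSO. Spry4 rests on few counts, 18 in the 3 libraries of the pair and 76 in the 3 with all agents. YAP/TEAD targets were lower in 10 of 19, or 11 adjusted over the list alone (camera adjusted p = 1.47e-09; adjusted p = 0.0806 with an estimated correlation, or 0.00842 without APC restoration replicate 1), such as Amotl2 (-0.84 ± 0.13). Hippo pathway and TEAD genes were lower in 6 of 17, or 7 lower and 1 higher adjusted over the list alone (3.04e-05; adjusted p = 0.0806 with an estimated correlation). By the naming rule the largest rises were in Etv4, the claudin gene Cldn2 (1.26 ± 0.23) and the chemokine gene Cxcl5 (1.23 ± 0.14), and the largest falls in Eprn (-1.55 ± 0.19), Upk3b (-1.32 ± 0.19) and Mettl7b (-1.31 ± 0.16). In all, 284 genes were higher and 700 lower. The total of 984 was 1768 without APC restoration replicate 1, 596, 557 and 530 without replicates 1, 2 and 3 of the pair, 529 without replicate 3 of the 3 agents and 1537 with no filter on low counts.

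Against the pair of divarasib and GNE-7883, adding APC restoration lowered Wnt/beta-catenin targets in 17 of 19, with 2 higher (camera adjusted p = 1.92e-19; adjusted p = 0.000834 with an estimated correlation). It raised absorptive enterocyte markers in 17 of 21, or 18 adjusted over the list alone (1.46e-18; adjusted p = 0.00643 with an estimated correlation). Cell cycle genes rose in 19 of 29, or 23 adjusted over the list alone (camera adjusted p = 3e-05; adjusted p = 0.509 with an estimated correlation). Zg16 (5.86 ± 0.59), Clca1 (5.63 ± 0.45) and the carboxylesterase gene Ces2e (5.19 ± 0.47, or 6.41 without replicate 2 of divarasib with GNE-7883) rose most, and Vwa2 (-2.26 ± 0.32), Slc9a3 (-2.13 ± 0.28) and Pla2g2a (-1.80 ± 0.31) fell most, with 2291 genes higher and 2155 lower. A stricter filter turned this to 2119 and 2346, as did no filter (2080 and 2271) and leaving out replicate 2 of the 3 agents (1864 and 1945). Against the pair of APC restoration and GNE-7883, adding divarasib lowered ERK output in 13 of 16, with 2 higher (camera adjusted p = 1.67e-07; adjusted p = 0.295 with an estimated correlation, or 0.00331 without APC restoration replicate 1), and cell cycle genes in 29 of 29 (6.18e-43; adjusted p = 0.0723 with an estimated correlation, or 0.00959 without APC restoration replicate 1). Cym (5.53 ± 0.63), Tbx2 (4.02 ± 0.49) and Igfbp5 (3.94 ± 0.59) rose most, and Muc5ac (-3.83 ± 0.55), Tcf23 (-3.35 ± 0.36) and Slc16a3 (-3.11 ± 0.42) fell most, with 4550 genes higher and 4401 lower, or 4074 and 4315 with no filter and 4169 and 4295 without replicate 2 of the 3 agents.

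The 3-way interaction asks whether the divarasib and GNE-7883 interaction differed with APC restoration. Its 4 called genes were all positive. They were Tk1, thymidine kinase (1.04 ± 0.19), Gmnn, geminin (0.93 ± 0.17), Cdca3 (0.81 ± 0.15) and Gins2, a replication complex subunit (0.76 ± 0.12). None of 29 cell cycle list members was called over all genes, but 23 were positive adjusted over the list alone, with a median of 0.55 (camera adjusted p = 1.08e-33; adjusted p = 0.178 with an estimated correlation, or 0.0332 without APC restoration replicate 1). The count of 4 was 387 (314 positive, 73 negative) without APC restoration replicate 1, with 20 cell cycle members called, 27 without replicate 3 of the 3 agents, and 0 to 2 without each of 21 other libraries. The calls of Tk1 and Gmnn ended without each of 21 libraries and that of Cdca3 without each of 22 (edgeR adjusted p up to 0.15, Tk1 without replicate 2 of divarasib with GNE-7883), and that of Gins2 without each of 5 (up to 0.0633, without the same library). DESeq2's Wald test called 38 genes and edgeR with no filter on low counts 341.

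Responses to the same agent were compared between contrasts that share no library, by Pearson correlation of log2 fold changes across genes, which are not independent replicates. The median over 6 pairs of contrasts was 0.867 for divarasib, 0.737 for APC restoration and 0.234 for GNE-7883. These same-agent pairs ran from 0.854 to 0.91, 0.613 to 0.776 and 0.054 to 0.314 in that order. The values for GNE-7883 thus overlap those between different agents. Between different agents the medians over 8 pairs each were 0.087 (divarasib and APC restoration), -0.065 (divarasib and GNE-7883) and -0.059 (APC restoration and GNE-7883). The pairs ran from -0.233 to 0.369, -0.393 to 0.281 and -0.19 to 0.041 in that order. Without APC restoration replicate 1 they ran from -0.24 to 0.211, -0.308 to 0.28 and -0.144 to 0.041, with medians of 0.064, 0.138 and -0.1045. The pair at -0.393, divarasib against DMSO and GNE-7883 added to APC restoration, was then 0.131. Markers of cells other than epithelium were scarce. Of 34 such markers in the lists 14 were tested, and 2 exceeded 10 CPM in any group, Fn1 (342 CPM at its highest group mean) and Cd14 (85.7 CPM), while the 13 epithelial markers had means of 36.61 to 2635 CPM. Fibroblast and mesenchymal markers were higher in 4 of 7 with divarasib (camera adjusted p = 0.294), higher in 1 and lower in 1 with APC restoration (0.868), and not called with GNE-7883 (0.648). Epithelial markers were higher in 11 of 13 and lower in 1 with divarasib (camera adjusted p = 0.000218; adjusted p = 0.343 with an estimated correlation). They were higher in 10 with APC restoration (1.65e-10; adjusted p = 0.0315 with an estimated correlation) and higher in 1 with GNE-7883, or 3 without APC restoration replicate 1 (0.0272; adjusted p = 0.392 with an estimated correlation). Of the 111 genes named, 8 overlap another expressed gene on the opposite strand in the annotation (Fosl1, Ccne2, Kras, Pla2g2a, Erbb2, Crim1, S100g and Gins2). Because the counting's strand setting is not stated, their counts may include reads of that neighbour. Over whole gene spans the overlap is 9 bases for Erbb2, 241 for Kras and 2608 to 7381 for the others. Genes of families with close copies, such as Gsta1, Cyp2c66, Ces2a, Ces2e, Clca1 and the Pla2g2 genes, are uncertain for another reason, as a read may match another copy.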

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

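The counts over other splits of the libraries, and the look at splits that give no agent any weight, were chosen after the results were seen. Each result here stands out because edgeR's test of the interaction found that the effect of 1 agent differed with another agent present.

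Divarasib and APC restoration had 955 genes with an interaction. Of 100 splits of the 12 libraries, 9 gave as many, the real one included, with a highest other count of 9022, but this says nothing about chance. Each other split put libraries of different treatments together in at least 3 groups, with a common biological coefficient of variation of 0.142 or more against 0.0642. Among called genes with a mean of at least 5 CPM, passing over predicted genes, Cyp4b1 (2.057) and Ppargc1a (1.136) had the largest positive interactions on the log2 scale and Upk3b (-2.306) and S100g (-2.231) the most negative. Without APC restoration replicate 1 these genes were at 1.968, 1.203, -1.895 and -1.861 in this order.

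Divarasib and GNE-7883 had 122 genes with an interaction. Of 100 splits, 7 gave as many, the real one included, with a highest other count of 9003, but this says nothing about chance. Here too each other split mixed treatments in at least 3 groups, with a common biological coefficient of variation of 0.151 or more against 0.0642. Among the called genes with a mean of at least 5 CPM, passing over predicted genes, Rnf39 (0.69) and Egr1 (0.606) had the largest positive interactions and Cenps (-0.915) and Krt79 (-0.851) the most negative, and the cell cycle list had a median interaction of -0.5. Leaving out 1 library gave totals from 27 to 367. It ended the call of Cenps for 10 libraries, Krt79 for 9, Egr1 for 6 and Rnf39 for 3.

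APC restoration and GNE-7883 had 17 genes with an interaction. Of 100 splits, 7 gave as many, the real one included, with a highest other count of 5198, but this says nothing about chance. Again each other split mixed treatments in at least 3 groups, with a common biological coefficient of variation of 0.105 or more against 0.0642. Igf2bp1 (0.579) and Abcc5 (0.433) were positive, and Prss32 (-0.748) and Nectin4 (-0.705) the most negative by the same rule. Leaving out 1 library gave totals from 0 to 699. It ended the calls of Igf2bp1, Prss32 and Nectin4 for 8 libraries each and that of Abcc5 for 5.

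The 3-way interaction had 4 genes, with Tk1 (1.038) and Gmnn (0.927) the highest. Of 100 splits of the 24 libraries, 3 gave as many, the real one included, with a highest other count of 4543, but this says nothing about chance. Each other split put libraries of different treatments together in at least 7 of the 8 groups, which raised the common biological coefficient of variation from 0.0642 to 0.21 or more, and 96 of the 99 called 0 genes by edgeR. The count of 4 was 2 with the replicate block, 0 without replicate 1 or 3 of divarasib, replicate 2 of divarasib with GNE-7883, or replicate 1 or 3 of APC restoration with GNE-7883 (1064 to 1289 genes at an unadjusted p under 0.05), and 38 by DESeq2's Wald test.

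Splits that called many more genes than the real one point to a structure of the samples, the agents themselves. In the others with as many genes, the effect of divarasib or APC restoration entered the contrast with a weight above 1 in 7 of 8 for divarasib and APC restoration, 6 of 6 for divarasib and GNE-7883, 6 of 6 for APC restoration and GNE-7883, and 2 of 2 for the 3-way interaction. The splits in which no agent had any weight (22, 22, 22 and 3 of them) called 0 genes, but they too mixed treatments within groups and had a higher coefficient of variation (0.177, 0.163, 0.11 and 0.24 or more), so they exclude nothing. No technical explanation for the interactions was tested.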

How the results depend on the processing

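The refits without APC restoration replicate 1 of results outside its own comparisons, of gene lists (with the preset and the estimated correlation) and of correlations were chosen after the data were seen. No gene was called in opposite directions under any alternative. Of 289 counts of called genes under alternatives, 204 were within 1.5 times the count reported, and DESeq2 size factors and the stricter filter moved none. DESeq2's Wald test gave 826 genes for GNE-7883 and 270 for it added to APC restoration. It gave 277, 224 and 38 for the interactions of divarasib with GNE-7883, of APC restoration with GNE-7883 and of all 3. No filter on low counts, which tests 31278 genes, gave 1247 for GNE-7883, 675 for it added to APC restoration and 1537 for it added to divarasib with APC restoration. For the interactions it gave 1573 for divarasib with APC restoration and 635, 821 and 341 for the other 3. A fit of only the compared groups, with fewer samples, gave 4308 for APC restoration, 1369 for GNE-7883, 3128 for it added to divarasib and 583 for the divarasib and GNE-7883 interaction. It gave 0 for GNE-7883 added to APC restoration and for their interaction (889 and 1780 at an unadjusted p under 0.05). A fit of the compared groups alone has fewer samples and estimates the spread from those groups only, and no filter tests other genes. Beyond that, the cause of a move was not tested.

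Leaving out 1 library moved 8 of the 20 counts by over 1.5 times. The ranges were 142 to 1425 for GNE-7883 against DMSO, 1250 to 3119 for it added to divarasib, 21 to 533 added to APC restoration and 529 to 1768 added to both. For the interactions they were 581 to 1999 (divarasib with APC restoration), 27 to 367 (divarasib with GNE-7883), 0 to 699 (APC restoration with GNE-7883) and 0 to 387 (all 3). The highest came without APC restoration replicate 1, or without its replicate 2 for 533, 1999 and 699. The lowest, in this order, came without GNE-7883 replicate 3, divarasib replicate 1, replicate 1 of APC restoration with GNE-7883, replicate 3 of all 3 agents, DMSO replicate 3, divarasib replicate 1 and, for the first 0, GNE-7883 replicate 1 or 3 (1741 and 1989 at an unadjusted p under 0.05). APC restoration replicate 1 is in neither group of GNE-7883 against DMSO, so it can act there only through the scaling and spread shared by all libraries. Without it that count rose from 523 to 1425 while the median log2 fold change moved by 0, so the rise came through the estimated spread. The same held for GNE-7883 added to divarasib (1986 to 3119, with the median moved by 0). The 846 higher and 1140 lower genes of GNE-7883 added to divarasib became 625 and 1346 with DESeq2 size factors. The larger of the higher and lower counts changed side in 11 of the 20 comparisons under at least 1 alternative. DESeq2 size factors moved the median of all genes by at most 0.0237 on the log2 scale, but the filters on low counts moved it further. For divarasib it moved by 0.0751 with the stricter filter and by 0.0666 with no filter. The share of called genes that were higher went from 49.78% to 56.24% and 56.87%. For APC restoration it moved by 0.0396 without APC restoration replicate 3, with a share from 46.98% to 55.32%.

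Gene list calls fell from 195 to 23 of 460 with an estimated correlation, or to 60 when APC restoration replicate 1 was also left out. The cause was not tested. The median correlations of responses became 0.9505 (divarasib), 0.847 (APC restoration) and 0.352 (GNE-7883) over genes with a mean of at least 5 CPM, and 0.5765 for APC restoration by Spearman correlation. Between divarasib and APC restoration the median of 0.087 became 0.157 over those genes and 0.1565 by Spearman correlation, and between divarasib and GNE-7883 -0.065 became -0.041 and 0.0035, or 0.138 without APC restoration replicate 1. Of 2528 values of named genes 2335 kept their direction and side of the threshold, 185 lost the call, 1 gained it and 7 changed sign, all of these uncalled. The cause was not tested. Kras with divarasib was -0.004 without divarasib replicate 3 (leave-one-out range to 0.051). Kras with APC restoration was -0.005, -0.025 and -0.004 without DMSO replicates 1, 2 and 3 and -0.016 without APC restoration replicate 1 (range to 0.057). Smad4 with APC restoration was 0.004 without its replicate 3 (range from -0.106) and with GNE-7883 0.01 without its replicate 2 (range from -0.037). Of 450 values of gene lists 362 were the same, 79 lost the call, 4 gained it and 5 changed direction, uncalled. The cell cycle list did so for GNE-7883 added to divarasib with APC restoration, with the replicate block (camera adjusted p = 0.983) and without APC restoration replicate 1 (0.881, or 0.968 with an estimated correlation). Without that library so did the interferon list for APC restoration (0.49, or 0.718).

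The replicate block moved 1 count by over 1.5 times, the 3-way interaction (2 in place of 4), and ended the calls of Tk1 (edgeR adjusted p = 0.0813) and Gmnn (0.101) there. Libraries with the same replicate number correlated at -0.00286 on average and those with different numbers at 0.00143. Of 84 same-number pairs 5 were over 0.1, so the numbers were not taken as pairs. Depth limits the folds of named genes with few counts, such as Cd36 with 3 counts over the DMSO libraries.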

Other observations

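The tests of a source without doxycycline and of a graded response for APC restoration replicate 1, the gene sets in its mixture test, the refits of the mitochondrially encoded list without each library, and the counts over other splits were chosen after the results were seen.

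Interferon response genes were higher in each group with divarasib than in DMSO. With divarasib alone 11 of 19 were higher and 1 lower (camera adjusted p = 0.0179; adjusted p = 0.483 with an estimated correlation). With APC restoration added 15 were higher and 1 lower (0.0189; adjusted p = 0.431 with an estimated correlation). With GNE-7883 added 13 were higher and 2 lower (0.00994; adjusted p = 0.501 with an estimated correlation), as with all 3 agents (0.0252; adjusted p = 0.422 with an estimated correlation). With APC restoration alone 4 were higher and 3 lower (camera adjusted p = 0.94), or 2 and 4 without APC restoration replicate 1 (0.49).

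Mitochondrially encoded genes had a median log2 fold change of 0.57 with GNE-7883, with 0 of 13 called by edgeR, or 11 higher adjusted over the list alone (camera adjusted p = 3.9e-07; adjusted p = 0.392 with an estimated correlation). Their median interaction was -1.05 for divarasib and GNE-7883, with 0 called by edgeR, or 13 lower adjusted over the list alone (2.28e-16; adjusted p = 0.087 with an estimated correlation). It was -0.90 for APC restoration and GNE-7883, with 12 lower adjusted over the list alone (1.92e-10; adjusted p = 0.592 with an estimated correlation), and 0.99 in the 3-way interaction (3.68e-08; adjusted p = 0.487 with an estimated correlation). Leaving out 1 library of the comparison, these medians ran from 0.353 to 0.708, -1.199 to -0.815, -1.072 to -0.671 and 0.786 to 1.142. The first was lowest without GNE-7883 replicate 1, a library in which these genes held 2.734% of the counts (2.105% and 1.861% in the other 2). Without that library the interaction medians were -0.815, -0.704 and 0.8 in the same order. Each of these interactions contains the difference between GNE-7883 and DMSO, so the medians are not separate findings.

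APC restoration replicate 1 lay between its group and divarasib with APC restoration. A swap with such a library is argued against by its share of 0.451 of that profile beside 0.997 to 1.005 in the 3 libraries of that group, and material from a divarasib library without doxycycline by Apc, at 1590 CPM where that share would leave 845.1 (1302 and 1382 in the other 2). Material from a library with both agents, or a graded response, may account for it. A mixture needs the same share in genes higher and lower with divarasib, and the median shares differed by 0.022, 0.18 and 0.269 in genes changed at least 2, 3 and 4-fold, where under 0.1 was needed and over 0.2 was to argue against it. Positions on the log scale, for a graded response, differed by 0.215, 0.185 and 0.152, so it missed the needed 0.1 in each set, was not over 0.2 in each, and neither source can be ruled in or out with these sets, which were chosen after an earlier set had been looked at.

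For the pairwise comparisons, the 10 splits of 6 libraries are too few for a share under 0.05, the real one being the 1 with the most genes in each. Each other split also mixed treatments in 2 groups and left the compared effect a weight of 0.333 or -0.333. For divarasib against DMSO the common biological coefficient of variation was then 0.154 or 0.155 against 0.0642. Low counts in the other splits were thus to be foreseen and say nothing about chance. Real counts and highest other counts against DMSO were 10378 and 0 (divarasib), 6909 and 130 (APC restoration) and 523 and 0 (GNE-7883). They were 10859 and 0 (divarasib with APC restoration), 10784 and 0 (divarasib with GNE-7883), 6095 and 0 (APC restoration with GNE-7883) and 10434 and 0 (all 3). Adding APC restoration to divarasib gave 4474 and 0, and adding divarasib to APC restoration 8926 and 0. Adding GNE-7883 to divarasib gave 1986 and 0, adding divarasib to GNE-7883 10729 and 0, adding GNE-7883 to APC restoration 95 and 73, and adding APC restoration to GNE-7883 4981 and 0. For the third agent added to a pair, GNE-7883 gave 984 and 1, APC restoration 4446 and 42, and divarasib 8951 and 0.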
